A study of Rattus with 8 samples.

How the data were processed

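Messenger RNA of cultured rat neural stem cells was sequenced on day 5 in 8 samples, 4 groups of 2, and each sample's group and replicate number were taken from its label. Per the labels' protocols, the authors enriched polyadenylated RNA with oligo(dT), fragmented it, primed complementary DNA with random hexamers and sequenced the libraries as DNA nanoballs. The authors deposited 1 table of the whole series with 18374 genes, which holds a read count, an FPKM and a TPM for each library, per the file headers. The deposited counts are estimated counts, since 10.5% of them are not whole at a tolerance of 0.005, and 2627 genes have such a count in at least 1 library, which points to reads divided between genes or transcripts. The FPKM and TPM columns that the authors deposited are scaled for transcript length and library, per the file headers, and were used only to derive effective lengths and to check the counts. The deposited log2 fold changes and the deposited p-values and q-values are the authors' own DESeq2 results, per the file headers, and were used only for a comparison with the edgeR calls. The genome build is Rnor 6.0, per the submitters' processing notes, and coordinates are those of the deposited table. The aligner, the quantification tool and the use of strand are not given in the sources used here, so overlapping and near-identical genes may trade reads. A deposited matrix of correlations was not used. Gene symbols came from the table, and 93.22% of its gene identifiers were found in a RefSeq gene table of a later assembly (GRCr8), whose coordinates were not used. No gene of the table lies on the mitochondrial chromosome.

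Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr, which kept 14336 genes, libraries were scaled with the trimmed mean of M values (TMM), dispersions were estimated robustly and 1 quasi-likelihood model was fitted to the 8 libraries with a mean per group, since a group alone leaves 1 residual degree of freedom. The fit had 4 residual degrees of freedom and a biological coefficient of variation of 7.09%. Each comparison used a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM factors and are given as mean ± SD of 2 libraries. The comparisons were each treated group with control, nanosticker with piezoelectric and with ultrasound, and the departure of the nanosticker change from the sum of the other changes on the log2 scale. Library totals differed little, so depth limits genes with few counts in a like way in the 4 groups.

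The design, the 33 gene lists (689 symbols, of which 683 matched the table, 4 by an older symbol or the RefSeq table), the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, for lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Counts of list genes are out of the members that passed the low-count filter, not of all symbols on the list. Named genes have an adjusted p below 0.05, a mean CPM of at least 5 in a group compared, no overlap between the libraries of the groups compared and no placeholder symbol. Of these the 8 largest increases and 8 largest decreases are named for each comparison with control, and 5 each for the others. Up to 4 members with the smallest adjusted p of each list described are named too, and always Sox2, Nes, Tubb3, Dcx, Map2, Rbfox3, Gfap, Olig2, Mki67, Fos, Bdnf, Cacna1c and Piezo1. For the departure from additivity all 4 groups count for the CPM minimum and overlap is not considered. Some further genes, mostly list members that moved against the rest of their list, were chosen after their values were seen, and so were the genes of the control group description. Some genes that the rule selects are not reported here. Genes with counts that are not whole are called uncertain or said to have shared reads.

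Alternatives were DESeq2 1.42.0, limma-voom, relative log expression size factors, library size alone, no filter and a stricter filter on low counts (1 CPM in 2 libraries and a mean count of 20), the replicate number as a block, a fit of only the groups compared, and each library left out in turn, where a group left with 1 library is assumed to vary like the others. Chosen after seeing the data were the removal of each library's trend along transcript length (lowess, span 0.3), the restriction to genes with whole counts, and the settings of the distances and correlations. The edgeR steps were tested on simulated counts, with 200 genes changed in the nanosticker group and another 200 in the piezoelectric group, so that nanosticker against piezoelectric and the departure from additivity held both sets. Over 14193 simulated genes, 80% of the 2-fold changes and 59.6% of those of log2 size 0.5 were recovered for nanosticker against control, 76% and 51.5% for piezoelectric against control, and 66% and 30.3% for the departure from additivity. Between 6.23% and 11.2% of calls were false in the simulated comparisons. A planted shift of 1 list was called by camera (adjusted p = 2.71e-18, and adjusted p = 0.0178 with an estimated correlation). Simulated genes varied independently of each other, so this did not test the preset correlation. With a length trend planted in the simulation of nanosticker against control, removing it raised the recovery of changes of log2 size 0.5 from 28.3% to 52.5%, and the share of false calls from 4.72% to 6.94%. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.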

Results

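RNA sequencing measured the messenger RNA of rat neural stem cells, the self-renewing precursors of neurons, astrocytes and oligodendrocytes, on day 5 of culture. The labels give 4 groups of 2 samples. One group was untreated (control), one was cultured with a piezoelectric material (piezoelectric), one was treated with ultrasound (ultrasound) and one was cultured with piezoelectric nanostickers (nanosticker). A piezoelectric material turns mechanical deformation into electric charge. The title of the series speaks of nanostickers that ultrasound activates, in the setting of traumatic brain injury. The labels do not say whether the nanosticker group received ultrasound, nor how its material differs from that of the piezoelectric group. They also do not say whether the samples of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The libraries held between 15239133 and 15628667 counts each. Between 16497 and 16613 of the 18374 genes had a count above 0.

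The control cells expressed genes of several neural lineages side by side. The stem cell genes Sox2, a transcription factor, and Nes, the intermediate filament nestin, stood at 281 ± 2.76 and 354 ± 58.5 CPM (reads of a gene scaled to a common library total, mean ± SD, n = 2). Gfap, the intermediate filament of astrocytes, stood at 1519.8 ± 66.2 CPM and Aqp4, their water channel, at 1649 ± 9.79 CPM. Mbp, which encodes myelin basic protein of oligodendrocytes, stood at 3735 ± 16.2 CPM. Among neuronal genes, Dcx, expressed by migrating young neurons, stood at 488 ± 41.8 CPM, Tubb3 at 214 ± 21.5 CPM and Rbfox3, a gene of mature neurons, at 6.19 ± 0.0796 CPM. Microglial transcripts were rare, with Csf1r at 3.77 ± 0.782 CPM and C1qc at 5.61 ± 0.922 CPM.

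The nanosticker libraries lay farthest from the controls. Over the 14336 tested genes, Euclidean distances of log2 CPM between control and nanosticker libraries ran from 81.3 to 85.7. Those between control and ultrasound libraries ran from 52.6 to 59.9, and those between control and piezoelectric libraries from 45.7 to 57.6. The control libraries lay 53.5 apart, against 44.2 to 45.3 within the other groups. The log2 ratio of control replicate 1 to control replicate 2 fell with transcript length (Spearman -0.601 across 10178 genes, which are not independent replicates), while the other groups gave 0.162 to 0.264. Values with this length trend removed, or without 1 of the controls, are therefore given where they move a count or end a call.

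**Figure D1:**
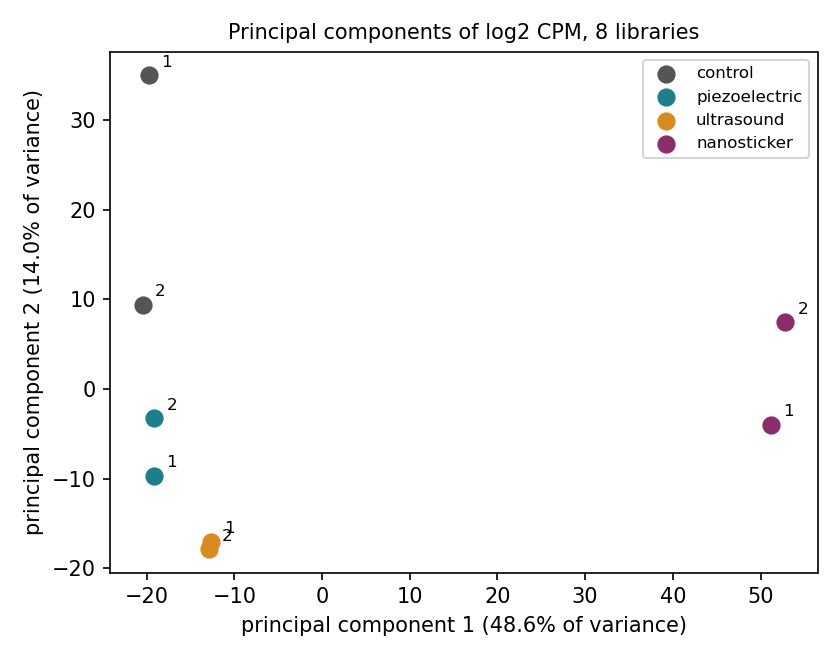
Principal components of log2 CPM over the tested genes, with 1 point per library, colored by group and numbered by replicate, and the share of variance on each axis. The first component (48.6%) separates the nanosticker libraries from the other 6, and the second (14.03%) runs from the ultrasound libraries (-17.1 and -17.9) to control replicate 1 (35.0), with control replicate 2 at 9.39.

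Cells cultured with the piezoelectric material were compared with untreated cells to see what the material changed in the absence of the nanosticker label. Few genes changed, and 2 of 10 tested ependymal and choroid plexus genes and 4 of 12 tested fibroblast and meningeal genes were among those that rose. Ttr, which encodes transthyretin, the thyroid hormone carrier secreted by the choroid plexus, rose from 2.35 ± 0.506 to 48.1 ± 5.6 CPM (mean ± SD, n = 2). Its log2 fold change was 4.35 ± 0.17 (SE) with adjusted p = 4.32e-08 by edgeR's quasi-likelihood test. In the Rnor 6.0 coordinates of the deposited table it is gene identifier 24856, chromosome 18 from 15532963 to 15542180 on the minus strand. Cemip, which takes part in the breakdown of hyaluronan, rose by 1.39 ± 0.14 on the log2 scale (adjusted p = 0.000996). Sulf1, an extracellular heparan sulfate sulfatase, rose by 0.99 ± 0.09 (adjusted p = 0.000326) and the fibrillar collagen gene Col3a1 by 0.94 ± 0.10 (adjusted p = 0.00116).

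Gfap rose from 1519.8 ± 66.2 to 2506 ± 138 CPM (log2 fold change 0.72 ± 0.07, adjusted p = 0.000460). Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, fell from 176 ± 4.07 to 121 ± 4.41 CPM (log2 fold change -0.54 ± 0.06, adjusted p = 0.000996). Other large increases on the log2 scale were in Il1rl1, the interleukin 33 receptor (2.07), Col8a1 (1.70), Rflna (1.01) and Fgd5 (1.0). Other large decreases were in Gabrb1, a GABA receptor subunit (-0.76), Nrg1, a ligand of ErbB receptors (-0.72), Tmem130 (-0.63), Calb2 (-0.57) and Gstm2 (-0.56). Abcb1b, a drug efflux pump, was lower too (-0.59), but its reads were shared with other genes in the deposited counts, so the value is uncertain. The stem cell, neuronal and oligodendrocyte genes named in advance did not pass the test: Sox2 0.05, Nes 0.17, Tubb3 0.01, Dcx 0.04, Map2 -0.05, Rbfox3 -0.15 and Olig2 0.03. Neither did Mki67 (0.19), Fos (0.20), Bdnf (0.47), Cacna1c (-0.10) or Piezo1 (-0.03).

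Of 12 fibroblast and meningeal genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone). Camera called the fibroblast and meningeal list higher (adjusted p = 4.62e-08, and adjusted p = 0.111 with an estimated correlation). The members that rose were Col1a1 (0.71), Col3a1, the matrix protein gene Postn (1.3) and the growth factor gene Igf2 (1.41). Of 10 ependymal and choroid plexus genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone). Camera called the ependymal and choroid plexus list higher (adjusted p = 6.20e-05, and adjusted p = 0.339 with an estimated correlation). Beside Ttr the member that rose was Aqp1, a water channel of the choroid plexus (1.99). Of 21 p53 target genes, 0 rose and 2 fell (0 and 4 adjusted over the list alone). Camera called the p53 target list lower (adjusted p = 8.24e-05, and adjusted p = 0.132 with an estimated correlation). Ccng1 (-0.32) fell along with Cdkn1a. Of 20 oxidative stress genes, 0 rose and 1 fell (0 and 5 adjusted over the list alone). Camera called the oxidative stress list lower (adjusted p = 0.00177, and adjusted p = 0.657 with an estimated correlation). The member that fell was Srxn1, which encodes sulfiredoxin (-0.48). Of 14 microglia genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Camera called the microglia list lower (adjusted p = 0.00190, and adjusted p = 0.253 with an estimated correlation). Of 27 synapse genes, 0 rose and 0 fell (0 and 2 adjusted over the list alone). Camera called the synapse list lower (adjusted p = 0.0260, and adjusted p = 0.765 with an estimated correlation). Of 20 cholesterol synthesis genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Camera called the cholesterol synthesis list lower (adjusted p = 0.0328, and adjusted p = 0.620 with an estimated correlation). Of the members of these last 3 lists, 3, 5 and 2 had an unadjusted p below 0.05 by edgeR's test, and their medians were -0.48, -0.08 and -0.06.

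Of 14336 genes tested by edgeR, 33 changed, 23 higher and 10 lower. The calls of Ttr, Cemip, Sulf1, Col3a1 and Gfap held under every alternative and without any 1 of the 8 libraries. Of the 22 named calls, 13 ended without piezoelectric replicate 1 (adjusted p from 0.0790 to 0.543), with Il1rl1, Aqp1 and Srxn1 among them. Without piezoelectric replicate 2, 14 ended (adjusted p from 0.0606 to 0.299), with Col1a1, Igf2 and Postn among them. Without any 1 of the ultrasound or nanosticker libraries, 7 or 8 ended (adjusted p from 0.0645 to 0.130), with Col8a1, Nrg1 and Ccng1 among them. The count was 13 without either piezoelectric library, 18 without either nanosticker library, 21 without either ultrasound library, 204 without control replicate 1, 1131 without control replicate 2 and 138 with the length trend removed. Of the named calls, 16 (adjusted p from 0.0536 to 0.343) ended with only the groups compared in the fit, 9 (adjusted p from 0.0606 to 0.242) by limma-voom and 3 (adjusted p from 0.0558 to 0.173) by DESeq2.

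Several list calls of the piezoelectric group rested on single libraries. Without control replicate 1 the microglia list (camera adjusted p = 0.0795) and the oxidative stress list (adjusted p = 0.30) were no longer called. The synapse list was not called without any 1 library other than control replicate 1 and piezoelectric replicate 1, and pointed up without control replicate 2 (adjusted p = 0.842, against 0.406 without piezoelectric replicate 2). The cholesterol list was not called without control replicate 2 (adjusted p = 0.334), piezoelectric replicate 1 (0.147) or piezoelectric replicate 2 (0.0550).

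The ultrasound group was compared with untreated cells to see what ultrasound changed in the absence of a piezoelectric label. Of the tested list members, the genes that rose included 10 of 15 inflammatory, 13 of 22 interferon response and 5 of 12 fibroblast and meningeal genes. Those that fell included 6 of 26 genes of Notch and bone morphogenetic protein (BMP) signalling and 6 of 27 synapse genes. Lcn2, a secreted iron-sequestering protein of reactive astrocytes and inflamed tissue, rose from 8.16 ± 1.88 to 33.5 ± 1.61 CPM (mean ± SD, n = 2). Its log2 fold change was 2.04 ± 0.16 (SE) with adjusted p = 5.74e-05 by edgeR's quasi-likelihood test, and it is gene identifier 170496, chromosome 3 from 11414187 to 11417534 on the minus strand. The chemokine genes Ccl2 and Cxcl10 rose by 1.64 ± 0.16 (adjusted p = 6.48e-05) and 1.59 ± 0.19 (adjusted p = 0.000245) on the log2 scale, and the antiviral gene Rsad2 by 1.22 ± 0.16 (adjusted p = 0.000503). Among named genes the increase of largest size was in Lum, a matrix proteoglycan of connective tissue, from 0.548 ± 0.0446 to 6.60 ± 0.386 CPM (log2 fold change 3.57 ± 0.25, adjusted p = 4.55e-06). Lum is gene identifier 81682, chromosome 7 from 38820058 to 38826862 on the plus strand.

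Of 15 inflammatory genes tested, 10 rose and 0 fell (13 and 0 adjusted over the list alone). Camera called the inflammatory list higher (adjusted p = 2.54e-11, and adjusted p = 0.109 with an estimated correlation). Nfkbia, the inhibitor of NF-kappa B, was among them (0.70). Of 22 interferon response genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone). Camera called the interferon response list higher (adjusted p = 2.73e-11, and adjusted p = 0.111 with an estimated correlation). Gbp2 rose by 0.69 and Mx1, whose reads were shared with other genes, by 1.54. Of 12 fibroblast and meningeal genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone). Camera called the fibroblast and meningeal list higher (adjusted p = 0.000124, and adjusted p = 0.111 with an estimated correlation). Igf2 (1.52), Col3a1 (1.09) and Col1a1 (0.61) were higher and the small proteoglycan gene Ogn (-0.32) lower. Of 26 Notch and BMP genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone). Camera called the Notch and BMP list lower (adjusted p = 0.000165, and adjusted p = 0.111 with an estimated correlation). The lower genes included the Notch effector gene Hes5 (-1.14), the Notch ligand gene Jag2 (-0.86), Bmp4 (-0.42) and Id3, a target of BMP signalling (-0.31). Nog, which encodes the BMP antagonist noggin, was also lower (-0.65), with reads shared between genes. Of 27 synapse genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone). Camera called the synapse list lower (adjusted p = 0.000358, and adjusted p = 0.420 with an estimated correlation). The vesicular GABA transporter gene Slc32a1 (-0.56) and the glutamate receptor genes Gria3 (-0.56) and Grin1 (-0.46) were among them.

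Glial genes moved in both directions. The myelin genes Mbp, Mag and Mobp rose by 0.48, 0.50 and 0.46, while Sox10, a transcription factor of the whole oligodendrocyte lineage, fell by 0.54. Of 17 oligodendrocyte genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone). The oligodendrocyte list was not called by camera (adjusted p = 0.0618, and adjusted p = 0.236 with an estimated correlation). Gfap rose by 0.69 ± 0.07 (adjusted p = 5.81e-05) and the hyaluronan receptor gene Cd44 by 0.49. Gja1, the gap junction protein connexin 43 of astrocytes, and Aldh1l1 were lower (-0.50 and -0.64). Of 13 astrocyte genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone). The astrocyte list was not called by camera (adjusted p = 0.701, and adjusted p = 0.837 with an estimated correlation). Its median was 0.03 and its mean -0.01, and the test pointed down. The intermediate filament genes Nes (0.41) and Vim (0.42) rose. Of 18 stem and progenitor genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone). The stem and progenitor list was not called by camera (adjusted p = 0.262, and adjusted p = 0.578 with an estimated correlation). Of 14 microglia genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). The microglia list was not called by camera (adjusted p = 0.654, and adjusted p = 0.806 with an estimated correlation). By edgeR's test 2 microglia genes had an unadjusted p below 0.05.

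Immediate early genes are the rapid transcriptional response to stimulation. Of 23 immediate early genes, 5 rose and 3 fell (8 and 3 adjusted over the list alone). Camera called the immediate early list higher (adjusted p = 0.0436, and adjusted p = 0.236 with an estimated correlation). Fos rose from 44.8 ± 0.403 to 81.8 ± 0.292 CPM (0.87 ± 0.07, adjusted p = 1.03e-05), Junb by 0.76 and Atf3, with shared reads, by 0.98. Ccn1 (-0.63), Dusp1 (-0.50), a phosphatase that shuts off MAP kinases, and Nr4a1 (-0.37) were lower. Ccn1 is also a target of the YAP coactivator. Of 14 Hippo and YAP genes, 0 rose and 4 fell (2 and 6 adjusted over the list alone). Camera called the Hippo and YAP list lower (adjusted p = 0.00737, and adjusted p = 0.236 with an estimated correlation). The others were Crim1 (-0.50), Ajuba (-0.50) and Amotl2 (-0.27). Of 26 cell cycle genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone). Camera called the cell cycle list higher (adjusted p = 0.00140, and adjusted p = 0.210 with an estimated correlation). These were Aurkb (0.50) and Top2a (0.23). Of 15 mechanosensitive channel genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone). Camera called the mechanosensitive channel list higher (adjusted p = 0.0436, and adjusted p = 0.236 with an estimated correlation). The member that rose was Kcnk10 (0.59), and Piezo1 stood at 0.52 with adjusted p = 0.0644. Of 20 cholesterol synthesis genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone). Camera called the cholesterol synthesis list lower (adjusted p = 0.00994, and adjusted p = 0.255 with an estimated correlation). That member was Dhcr7 (-0.24).

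edgeR called 1031 genes, 578 higher and 453 lower, against 509 higher and 519 lower with library size alone. Beside Lum and Lcn2, the largest increases among genes that met the naming rule were Grem1 2.62, Il1rl1 2.42, Ttr 2.17, Gda 1.80, Tf 1.77 and Thbs2 1.70, of which Grem1 encodes a BMP antagonist and Tf the iron carrier transferrin. Beside Hes5, the largest decreases were Gstm2 -1.75, Gldn -1.25, Ano5 -1.24, Pnlip -1.22, Col22a1 -1.21, Fmod -1.19 and Tinagl1 -1.14. Stmn2 (0.47), a growth cone protein, rose and the calcium channel gene Cacna1c (-0.43) fell. The genes Sox2 (-0.09), Tubb3 (-0.21), Dcx (-0.11), Map2 (-0.19), Rbfox3 (-0.25), Olig2 (-0.12), Mki67 (0.24) and Bdnf (0.47) did not pass. The count was 377 and 395 without ultrasound replicates 1 and 2, and 1766 and 2192 without control replicates 1 and 2. It was 1584 with the length trend removed and 636 by DESeq2.

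Of the 60 named ultrasound calls, 14 ended without ultrasound replicate 1 (adjusted p from 0.0583 to 0.329), among them Id3, Bmp4, Nog, Stmn2, Tinagl1, Cacna1c and Gda. Without ultrasound replicate 2, 13 ended (adjusted p from 0.0513 to 0.210), among them Hes5, Id3, Slc32a1, Grin1 and Crim1. Nes, Top2a and Ina did not pass without any 1 of the piezoelectric or nanosticker libraries either (adjusted p from 0.0596 to 0.0755). With only the groups compared in the fit 7 calls (adjusted p from 0.0730 to 0.168) ended, Nes, Id3 and Dhcr7 among them. Cacna1c did not pass with the length trend removed (adjusted p = 0.105), although its log2 fold change of -0.47 was no smaller in size. The mechanosensitive channel list was not called without control replicate 1 (camera adjusted p = 0.129), ultrasound replicate 1 (0.0509), ultrasound replicate 2 (0.113), piezoelectric replicate 1 (0.0589) or piezoelectric replicate 2 (0.0612). The immediate early list was not called without control replicate 1 (adjusted p = 0.0987), control replicate 2 (0.186), ultrasound replicate 1 (0.0859), ultrasound replicate 2 (0.122), nanosticker replicate 1 (0.0753) or nanosticker replicate 2 (0.0782). Without control replicate 2 the synapse (adjusted p = 0.205), Hippo and YAP (0.0857) and cholesterol (0.108) lists lost their calls. The cholesterol list also lost its call without ultrasound replicate 1 (adjusted p = 0.0864).

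**Figure D2:**
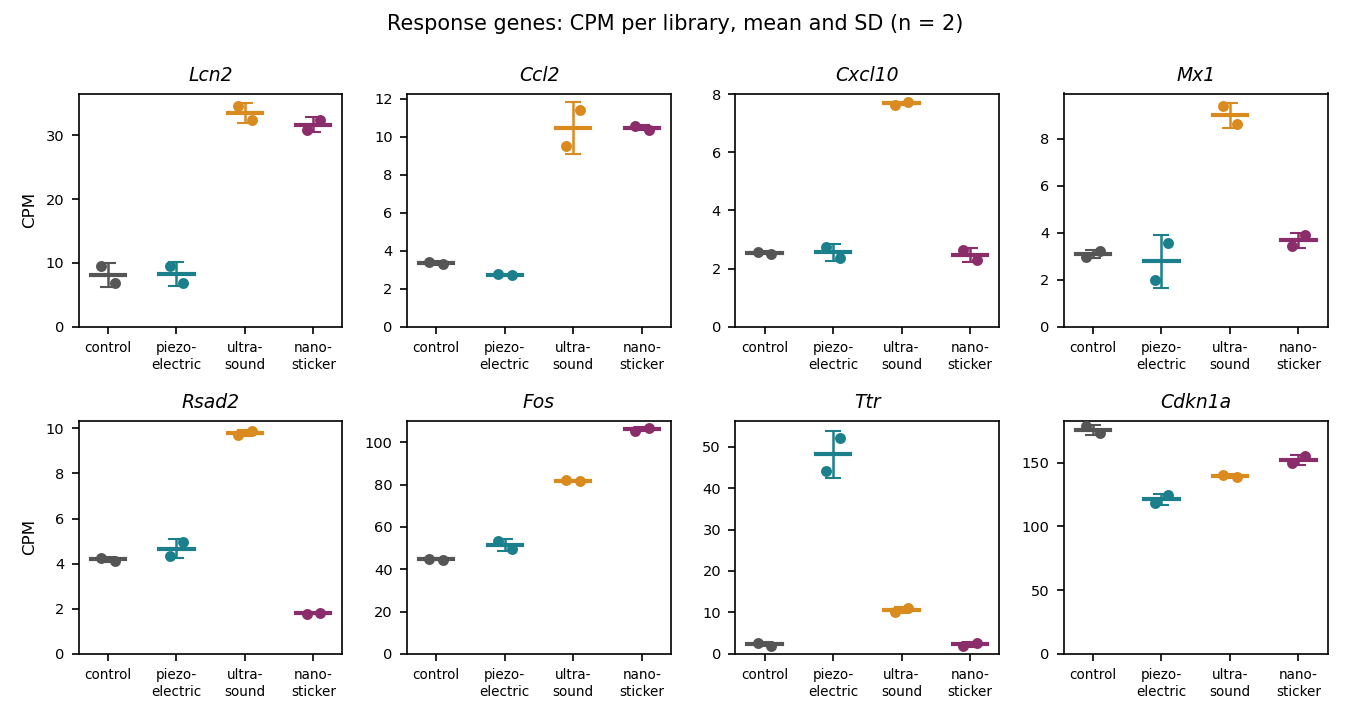
CPM of 8 response genes in the 4 groups, with 1 point per library, a bar at the mean, error bars of 1 SD (n = 2) and axes that start at 0. The ultrasound means are highest for Cxcl10, Mx1 and Rsad2 (7.68 against 2.55 CPM of Cxcl10 in control), ultrasound and nanosticker means are both above control for Lcn2, Ccl2 and Fos, and Ttr is highest in the piezoelectric group.

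The nanosticker group was set against untreated cells as the central comparison of the series. Genes of the oligodendrocyte lineage rose, and genes of astrocytes and of microglia fell. Mbp rose from 3735 ± 16.2 to 13678 ± 6.69 CPM (mean ± SD, n = 2), a log2 fold change of 1.87 ± 0.05 (SE) with adjusted p = 9.11e-11 by edgeR's quasi-likelihood test. Sox10 rose from 115 ± 1.36 to 459 ± 1.37 CPM (1.99 ± 0.06, adjusted p = 9.11e-11). Gja1 fell from 583 ± 4.74 to 146 ± 0.693 CPM (-2.0 ± 0.05, adjusted p = 6.55e-11). Dlx1, a homeobox regulator of GABAergic interneuron development, fell from 128 ± 7.49 to 9.29 ± 0.878 CPM (-3.78 ± 0.09, adjusted p = 3.86e-11). In Rnor 6.0, Mbp is gene identifier 24547, chromosome 18 from 79326738 to 79437310 on the plus strand. Sox10 is gene identifier 29361, chromosome 7 from 120393238 to 120403523 on the minus strand, and Gja1 is gene identifier 24392, chromosome 20 from 37876650 to 37889097 on the plus strand.

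Of 17 oligodendrocyte genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone). Camera called the oligodendrocyte list higher (adjusted p = 4.35e-11, and adjusted p = 0.0519 with an estimated correlation). Their median log2 fold change was 1.12, and they included the myelin gene Mag (2.10 ± 0.06) and the lineage factor Olig2 (0.31 ± 0.05, adjusted p = 0.000650). Of 13 astrocyte genes, 2 rose and 9 fell (2 and 9 adjusted over the list alone). Camera called the astrocyte list lower (adjusted p = 0.00556, and adjusted p = 0.257 with an estimated correlation). With a median of -0.52, this list held Aqp4 (-1.17), Slc1a3 (-0.85), S100b (-0.78) and Gfap (-0.50 ± 0.07, adjusted p = 5.96e-05) lower. Glul, which encodes glutamine synthetase, and Cd44 rose by 0.46 and 0.73. Of 14 microglia genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone). Camera called the microglia list lower (adjusted p = 2.02e-06, and adjusted p = 0.105 with an estimated correlation). Their median was -3.46, or -3.20 with Cx3cr1, which had no counts in the nanosticker libraries, set to its bound. C1qc fell from 5.61 ± 0.922 to 0.234 ± 0.0503 CPM and C1qa from 4.10 ± 1.15 to 0.234 ± 0.0442 CPM. Csf1r, the receptor microglia need to survive, fell from 3.77 ± 0.782 to 0.435 ± 0.147 CPM.

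Of 18 stem and progenitor genes, 3 rose and 10 fell (3 and 10 adjusted over the list alone). The stem and progenitor list was not called by camera (adjusted p = 0.0596, and adjusted p = 0.381 with an estimated correlation). Sox2 rose by 0.51 ± 0.06 (adjusted p = 1.37e-05), Pax6 (-1.06), Egfr (-0.88) and the radial glial gene Fabp7 (-0.84) fell, and Nes did not pass (-0.18, adjusted p = 0.170). Of 19 neuronal genes, 5 rose and 8 fell (5 and 8 adjusted over the list alone). The neuronal list was not called by camera (adjusted p = 0.171, and adjusted p = 0.381 with an estimated correlation). Tubb3 fell from 214 ± 21.5 to 79.8 ± 2.61 CPM (-1.42 ± 0.07, adjusted p = 6.82e-09). Dcx (-1.3 ± 0.07), Map2 (-0.38 ± 0.05) and Rbfox3 (-0.64 ± 0.21) fell too, while Thy1 (1.62) and Elavl3 (0.72) rose. Of 27 synapse genes, 7 rose and 13 fell (8 and 14 adjusted over the list alone). Camera called the synapse list lower (adjusted p = 0.0387, and adjusted p = 0.529 with an estimated correlation). Gad1, which makes GABA, stood at -2.50, Slc32a1 at -2.57, the GABA receptor gene Gabbr1 at -0.87 and Nrxn3 at -1.58. The synapse call was lost without control replicate 2 (adjusted p = 0.305), nanosticker replicate 1 (0.0553), nanosticker replicate 2 (0.0677), ultrasound replicate 1 (0.0656), ultrasound replicate 2 (0.0678) or piezoelectric replicate 2 (0.0756). The microglia genes fell beside these groups, with a median of -3.46 on the log2 scale.

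**Figure D3:**
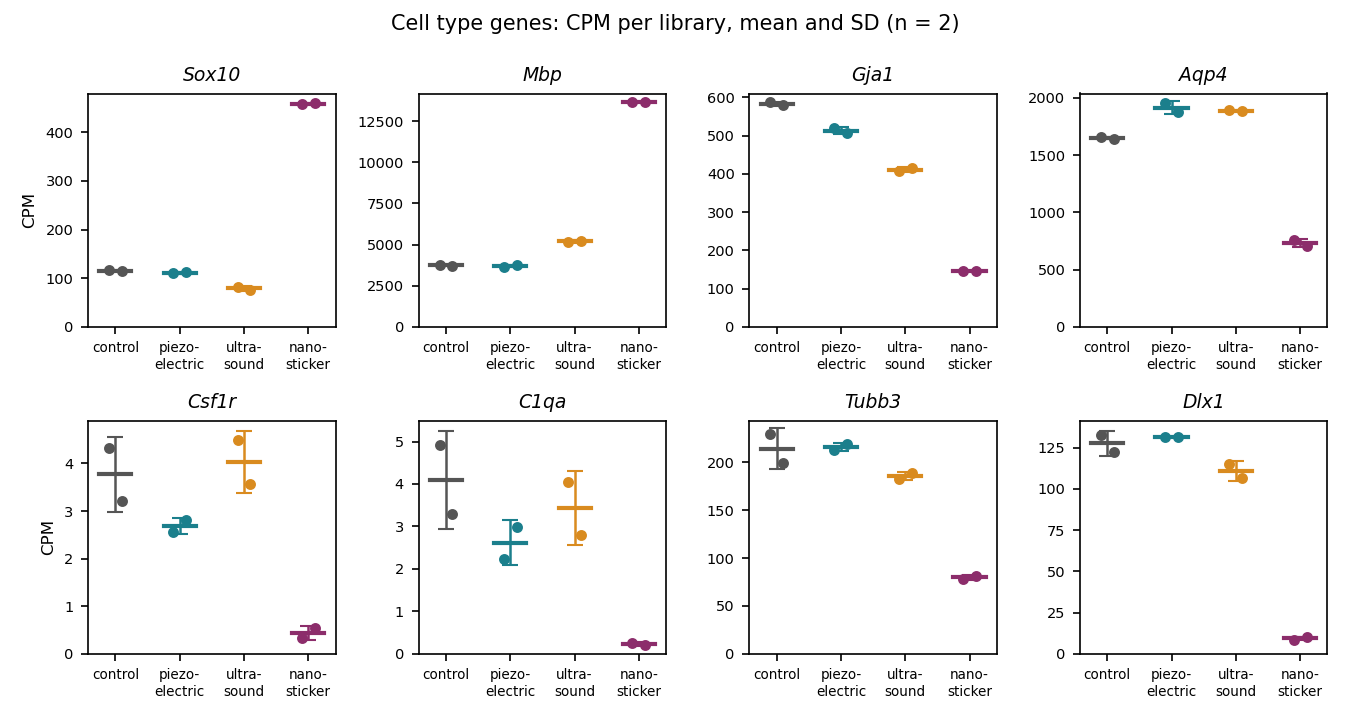
CPM of 8 cell type genes in the 4 groups, with 1 point per library, a bar at the mean, error bars of 1 SD (n = 2) and axes that start at 0. In the nanosticker libraries Sox10 and Mbp are highest (13678 CPM of Mbp) and Gja1, Aqp4, Csf1r, C1qa, Tubb3 and Dlx1 are lowest (9.29 CPM of Dlx1), with no overlap with the libraries of the other groups.

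Of 26 cell cycle genes, 17 rose and 1 fell (18 and 2 adjusted over the list alone). Camera called the cell cycle list higher (adjusted p = 0.000712, and adjusted p = 0.257 with an estimated correlation). Aurkb (0.85), Ccnd1 (0.74), Top2a (0.56) and Rrm2 (0.46) were higher, and Mcm7, a replication licensing helicase subunit, was lower (-0.22). Mki67, with shared reads, rose by 0.46 ± 0.11. Of 20 oxidative stress genes, 2 rose and 11 fell (3 and 11 adjusted over the list alone). Camera called the oxidative stress list lower (adjusted p = 0.00857, and adjusted p = 0.447 with an estimated correlation). Slc7a11, the cystine transporter gene (-1.96), Srxn1 (-1.33), Nqo1 (-1.11) and Gclc (-0.98) are targets of the transcription factor NRF2 and fell, while Gclm (0.29) rose. Without control replicate 1 the oxidative stress list was no longer called (adjusted p = 0.0550). Of 28 lysosome and endocytosis genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone). Camera called the lysosome and endocytosis list higher (adjusted p = 0.00980, and adjusted p = 0.381 with an estimated correlation). The cholesterol exporter gene Npc1 (0.81), Cav1 (0.85) and the protease gene Ctsl (0.67) were higher and Psap, the precursor of saposins, lower (-0.38). Of 12 fibroblast and meningeal genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone). Camera called the fibroblast and meningeal list higher (adjusted p = 0.0156, and adjusted p = 0.257 with an estimated correlation). Igf2 (4.8), Lum (2.92) and Col3a1 (1.93) were among them. Beside these groups the microglia median was -3.46.

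Stimulus genes and ion channels changed member by member, and camera called none of these lists. Over all tested genes, 5378 of 14336 were called. The share called was below this among mechanosensitive channel genes and calcium and CREB genes, and above it in the other lists of this paragraph. Of 23 immediate early genes, 9 rose and 2 fell (camera adjusted p = 0.178, 10 and 2 adjusted over the list alone). Fos rose from 44.8 ± 0.403 to 106 ± 0.974 CPM (1.25 ± 0.07, adjusted p = 1.23e-08), Junb by 1.28 and Egr1 by 0.64, and Ccn1 was lower (-1.01). Of 15 mechanosensitive channel genes, 4 rose and 0 fell (camera adjusted p = 0.126, 4 and 0 adjusted over the list alone). Piezo1, the mechanically gated cation channel, rose by 0.69 ± 0.15 (adjusted p = 0.00344), Piezo2 by 1.66 ± 0.54, Tmem63b by 0.32 and Trpc1, with shared reads, by 0.97. Of 20 voltage-gated calcium channel genes, 5 rose and 8 fell (camera adjusted p = 0.365, 5 and 9 adjusted over the list alone). Cacna1c fell by 1.0 ± 0.09 (adjusted p = 1.22e-06), and Cacnb4 (-0.79) and Cacng2, an auxiliary subunit of AMPA receptors (-3.89), were lower as well. Cacna1h, with shared reads, was higher (0.86). Of 20 growth factor genes, 8 rose and 4 fell (camera adjusted p = 0.106, 8 and 4 adjusted over the list alone), and Bdnf did not pass (0.53, adjusted p = 0.567). Of 17 sodium and potassium channel genes, 4 rose and 6 fell (camera adjusted p = 0.378, 5 and 6 adjusted over the list alone), and of 26 calcium and CREB genes, 4 rose and 5 fell (camera adjusted p = 0.917, 4 and 5 adjusted over the list alone). The microglia median beside them was -3.46.

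Camera called none of the remaining lists either, for which counts of higher and lower genes are given in that order, where 5378 of all 14336 tested genes were called. In signalling they were 7 and 15 of 26 Notch and BMP genes (adjusted p = 0.126, 7 and 15 adjusted over the list alone), 1 and 5 of 17 Wnt genes (adjusted p = 0.338, 1 and 5 adjusted over the list alone) and 2 and 5 of 14 Hippo and YAP genes (adjusted p = 0.287, 2 and 5 adjusted over the list alone). Contact and growth lists gave 7 and 11 of 24 axon guidance genes (adjusted p = 0.378, 7 and 11 adjusted over the list alone), 8 and 9 of 28 integrin and matrix genes (adjusted p = 0.979, 8 and 9 adjusted over the list alone) and 5 and 3 of 24 PI3K, Akt and mTOR genes (adjusted p = 0.404, 5 and 3 adjusted over the list alone). Immune lists gave 7 and 2 of 15 inflammatory genes (adjusted p = 0.128, 7 and 2 adjusted over the list alone) and 2 and 10 of 22 interferon response genes (adjusted p = 0.0523, 3 and 10 adjusted over the list alone). Stress lists gave 6 and 3 of 21 p53 target genes (adjusted p = 0.378, 6 and 3 adjusted over the list alone), 1 and 4 of 14 heat shock genes (adjusted p = 0.178, 1 and 4 adjusted over the list alone) and 10 and 8 of 23 unfolded protein and integrated stress genes (adjusted p = 0.938, 11 and 8 adjusted over the list alone). Metabolic lists gave 11 and 3 of 20 cholesterol synthesis genes (adjusted p = 0.0748, 12 and 3 adjusted over the list alone), 3 and 7 of 25 hypoxia and glycolysis genes (adjusted p = 0.615, 3 and 7 adjusted over the list alone) and 3 and 0 of 30 oxidative phosphorylation genes (adjusted p = 0.792, 1 and 0 adjusted over the list alone). Metal handling gave 2 and 6 of 12 such genes (adjusted p = 0.623, 3 and 6 adjusted over the list alone). Other cell types gave 3 and 2 of 7 endothelial and mural genes (adjusted p = 0.799, 3 and 2 adjusted over the list alone) and 1 and 1 of 10 ependymal and choroid plexus genes (adjusted p = 0.974, 1 and 1 adjusted over the list alone). Median, mean and test differed in sign for 6 uncalled lists. They were -0.021, 0.23 and up for ependymal genes, -0.012, 0.01 and down for calcium and CREB genes, 0.015, -0.01 and down for integrin genes, 0.18, -0.02 and up for unfolded protein genes, 0.0010, -0.04 and down for hypoxia genes and -0.13, 0.57 and down for metal handling genes.

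edgeR called 5378 genes, 2837 higher and 2541 lower, with 1215 of them at least 2-fold. The total was 3774 by DESeq2, 4058 with only the groups compared in the fit and 6137 with the length trend removed. Scaling by library size alone gave 2277 higher and 3221 lower. Igf2, a fetal growth factor gene, rose most among genes that met the naming rule, from 1.23 ± 0.185 to 34.3 ± 0.924 CPM (4.8 ± 0.21, adjusted p = 2.91e-09). It was followed by Tnn, a tenascin of the extracellular matrix (4.70), Trh, the precursor of thyrotropin-releasing hormone (4.64), and the keratin gene Krt19 (4.20). Prex2, a Rac activator gene (3.87), Serpinb1a (3.52), Syt4 (3.45) and Scube1 (3.43) came next. Among genes that met the same rule, Prokr2, a prokineticin receptor that guides migrating olfactory bulb neuroblasts, fell most, from 78.0 ± 2.04 to 1.37 ± 0.254 CPM (-5.82 ± 0.13, adjusted p = 3.86e-11). It was followed by C1qc (-4.54), Amer3 (-4.08), Calb2, the calcium-binding protein calretinin of interneurons (-4.02), Xkr7 (-3.90), Dlx1, Fcrl2 (-3.76) and Dlx5 (-3.75). Igf2 is gene identifier 24483, chromosome 1 from 215828102 to 215839081 on the plus strand. Prokr2 is gene identifier 192649, chromosome 3 from 125006180 to 125021020 on the minus strand.

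Of 71 named nanosticker calls, 3 ended without nanosticker replicate 1, those of Mki67 (adjusted p = 0.0708), Rbfox3 (0.241) and Piezo2 (0.0540). Piezo2 also failed without control replicate 2 (adjusted p = 0.183), nanosticker replicate 2 (0.156) or ultrasound replicate 2 (0.0503). By DESeq2 neither Rbfox3 (adjusted p = 0.138) nor Piezo2 (0.191) passed, and with only the groups compared in the fit these and Mki67 did not (adjusted p from 0.0524 to 0.0678).

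**Figure D4:**
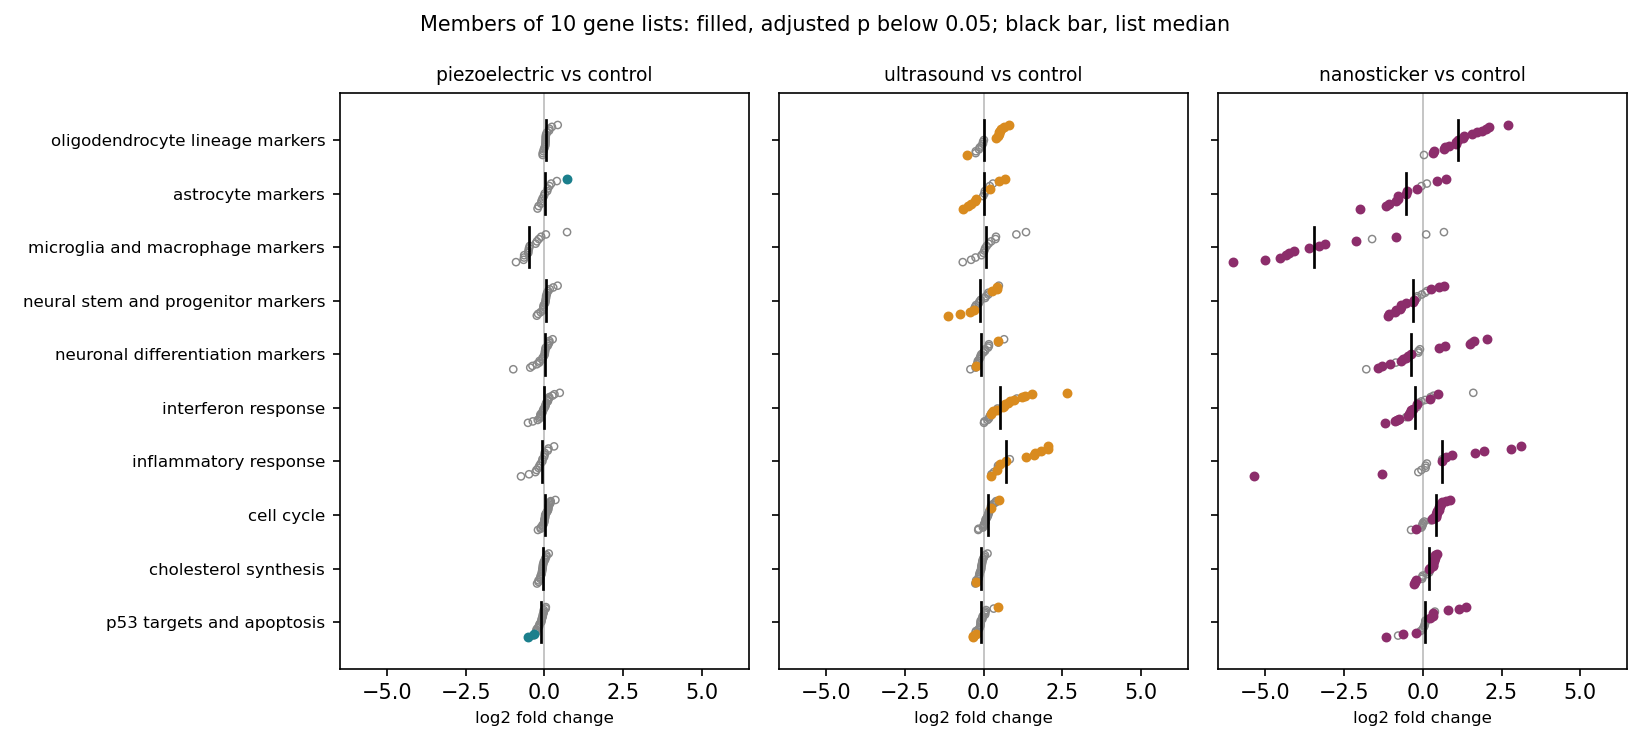
Log2 fold change against control of the tested members of 10 gene lists in the piezoelectric, ultrasound and nanosticker groups, where filled points have an adjusted p below 0.05 by edgeR, open points do not, and the black bar is the list median. Filled oligodendrocyte points lie right of 0 in the nanosticker panel (median 1.12) and filled microglia points left of it (median -3.46), while filled interferon and inflammatory points lie right of 0 in the ultrasound panel (medians 0.52 and 0.70).

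Set against the piezoelectric group, the nanosticker group was higher in oligodendrocyte genes and lower in astrocyte, progenitor and microglia genes. Of 17 oligodendrocyte genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone). Camera called the oligodendrocyte list higher (adjusted p = 8.32e-11, and adjusted p = 0.0545 with an estimated correlation). Mag stood at 2.09 ± 0.06, Sox10 at 2.05 ± 0.06 and Mbp at 1.89 ± 0.05 on the log2 scale (SE). Of 13 astrocyte genes, 2 rose and 8 fell (2 and 8 adjusted over the list alone). Camera called the astrocyte list lower (adjusted p = 0.00278, and adjusted p = 0.223 with an estimated correlation). Gja1 (-1.82), Aqp4 (-1.39) and Gfap (-1.22 ± 0.07) were lower. Of 18 stem and progenitor genes, 2 rose and 11 fell (3 and 12 adjusted over the list alone). Camera called the stem and progenitor list lower (adjusted p = 0.0292, and adjusted p = 0.294 with an estimated correlation). Egfr (-1.0) and Fabp7 (-0.81) were lower, and Sox2 (0.45) and Id1, a BMP target (0.80), higher. Of 14 microglia genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone). Camera called the microglia list lower (adjusted p = 1.09e-05, and adjusted p = 0.130 with an estimated correlation). Their median was -3.09, or -2.70 with Cx3cr1 at its bound.

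Of 26 cell cycle genes, 14 rose and 1 fell (17 and 2 adjusted over the list alone). Camera called the cell cycle list higher (adjusted p = 0.00151, and adjusted p = 0.223 with an estimated correlation). Of 28 lysosome and endocytosis genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). Camera called the lysosome and endocytosis list higher (adjusted p = 0.00278, and adjusted p = 0.294 with an estimated correlation). Of 20 cholesterol synthesis genes, 12 rose and 2 fell (14 and 3 adjusted over the list alone). Camera called the cholesterol synthesis list higher (adjusted p = 0.00943, and adjusted p = 0.294 with an estimated correlation). Of 21 p53 target genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone). Camera called the p53 target list higher (adjusted p = 0.0178, and adjusted p = 0.223 with an estimated correlation). Higher members were Ccnd1 (0.85), Npc1 (0.78), Srebf2, the master regulator of cholesterol synthesis (0.44), and Gadd45a (1.39). Btg2, an antiproliferative p53 target, was lower (-1.14), as were Fas (-0.42), a death receptor, and the cholesterol synthesis genes Sc5d (-0.21) and Cyp51 (-0.16). Beside these groups the microglia median was -3.09. edgeR called 5212 genes, 2713 higher and 2499 lower, with 1156 of them at least 2-fold, and library size alone gave 2273 higher and 3045 lower. DESeq2 called 3698 in all, against 6336 with only the groups compared in the fit and 5943 with the length trend removed.

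The largest named differences between nanosticker and piezoelectric libraries were Tnn 4.97, Trh 4.22, Serpinb1a 3.75, Prex2 3.58 and Krt19 3.48 upward. Downward they were Prokr2 -5.74, Ttr -4.38, Amer3 -3.84, Xkr7 -3.83 and Dlx1 -3.82. Tubb3 (-1.43), Dcx (-1.34), Map2 (-0.33) and Cacna1c (-0.90) fell. Olig2 (0.28), Fos (1.045) and Piezo1 (0.72) rose, and Rbfox3 (-0.48), Bdnf (0.06) and Mki67 (0.27) did not pass. Of 50 named calls that of Nes (-0.35) alone ended without 1 library. Its adjusted p was 0.109 and 0.0638 without piezoelectric replicates 1 and 2, and 0.0814 and 0.102 without nanosticker replicates 1 and 2.

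Against the ultrasound group, the nanosticker group had higher oligodendrocyte genes and lower interferon, astrocyte and microglia genes. Of 17 oligodendrocyte genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone). Camera called the oligodendrocyte list higher (adjusted p = 1.67e-09, and adjusted p = 0.0693 with an estimated correlation). Sox10 stood at 2.53 ± 0.06, Mag at 1.59 ± 0.06 and Ugt8, an enzyme of myelin galactolipid synthesis, at 1.34 ± 0.05 on the log2 scale (SE). Of 22 interferon response genes, 0 rose and 17 fell (0 and 18 adjusted over the list alone). Camera called the interferon response list lower (adjusted p = 2.55e-08, and adjusted p = 0.247 with an estimated correlation). Rsad2 fell from 9.80 ± 0.146 to 1.80 ± 0.0238 CPM (-2.44 ± 0.18, adjusted p = 3.44e-07), and Isg15 (-1.80) and B2m (-0.55) were lower. Of 14 microglia genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone). Camera called the microglia list lower (adjusted p = 4.36e-08, and adjusted p = 0.0712 with an estimated correlation). Their median was -3.50, or -3.27 with Cx3cr1 at its bound. Of 13 astrocyte genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone). Camera called the astrocyte list lower (adjusted p = 0.00874, and adjusted p = 0.274 with an estimated correlation). Gja1 (-1.5) and Gfap (-1.19) were among them.

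Of 20 oxidative stress genes, 3 rose and 14 fell (3 and 14 adjusted over the list alone). Camera called the oxidative stress list lower (adjusted p = 0.00410, and adjusted p = 0.478 with an estimated correlation). Slc7a11 (-1.39) and Hmox1 (-0.62) were lower, and the catalase gene Cat (0.32), Mgst1 (0.30) and Gclm (0.39) higher. Of 20 cholesterol synthesis genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone). Camera called the cholesterol synthesis list higher (adjusted p = 0.00374, and adjusted p = 0.274 with an estimated correlation). Of 26 cell cycle genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone). Camera called the cell cycle list higher (adjusted p = 0.0104, and adjusted p = 0.274 with an estimated correlation). Of 21 p53 target genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone). Camera called the p53 target list higher (adjusted p = 0.0361, and adjusted p = 0.274 with an estimated correlation). Of 28 lysosome and endocytosis genes, 10 rose and 2 fell (13 and 3 adjusted over the list alone). Camera called the lysosome and endocytosis list higher (adjusted p = 0.0455, and adjusted p = 0.459 with an estimated correlation). Dhcr7 (0.62), Cdk1 (0.39), Gadd45a (1.09) and Tfeb, a regulator of lysosomal genes (0.74), were higher. Tyms, a thymidylate synthesis gene (-0.55), Btg2 (-1.13) and Psap (-0.27) were lower. The p53 list was not called without ultrasound replicate 2 (adjusted p = 0.0543) or nanosticker replicate 2 (0.10). Neither was the lysosome list without ultrasound replicate 1 (adjusted p = 0.0841), ultrasound replicate 2 (0.0543) or nanosticker replicate 2 (0.0949). The microglia median beside these groups was -3.50.

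edgeR called 4938 genes, 2517 higher and 2421 lower, with 1009 of them at least 2-fold, and 3199 without ultrasound replicate 1. Library size alone gave 2121 higher and 2920 lower. The largest named differences were Tnn 4.0, Sostdc1 3.95, Krt19 3.92, Igf2 3.28 and Trh 2.94 upward and Prokr2 -5.41, Amer3 -4.0, Dlx1 -3.57 and Calb2 -3.48 downward. Zbtb33 had no counts in the nanosticker libraries and was at least 25.7-fold lower at a floor of 3 counts per library, with reads shared between genes. Sox2 (0.60), Olig2 (0.43) and Fos (0.38) were higher than with ultrasound. Nes (-0.59), Tubb3 (-1.22), Dcx (-1.19) and Cacna1c (-0.57) were lower, and Rbfox3 (-0.38), Mki67 (0.22), Bdnf (0.06) and Piezo1 (0.17) did not pass. Of 54 named calls that of Map2 (-0.20) alone ended without 1 library. Its adjusted p was 0.0604 without ultrasound replicate 1, 0.0990 without ultrasound replicate 2 and 0.125 without nanosticker replicate 2.

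Whether the nanosticker change differed from the sum of the piezoelectric and ultrasound changes was tested as an interaction on the log2 scale, although the labels do not say that the nanosticker group combines the single treatments. Most oligodendrocyte genes stood above the sum, and most microglia and interferon response genes and 6 of 13 astrocyte genes below it. Of 17 oligodendrocyte genes, 14 lay above the sum and 0 below it (14 and 1 adjusted over the list alone). Camera called the oligodendrocyte list higher (adjusted p = 7.26e-09, and adjusted p = 0.0789 with an estimated correlation). Sox10 departed by 2.59 ± 0.08, Mag by 1.59 ± 0.08 and Mbp by 1.41 ± 0.07 (SE). Of 14 microglia genes, 0 lay above the sum and 10 below it (0 and 11 adjusted over the list alone). Camera called the microglia list lower (adjusted p = 3.54e-07, and adjusted p = 0.0893 with an estimated correlation). Of 22 interferon response genes, 0 lay above the sum and 13 below it (0 and 15 adjusted over the list alone). Camera called the interferon response list lower (adjusted p = 3.54e-07, and adjusted p = 0.238 with an estimated correlation). Of 13 astrocyte genes, 1 lay above the sum and 6 below it (1 and 6 adjusted over the list alone). Camera called the astrocyte list lower (adjusted p = 0.0108, and adjusted p = 0.272 with an estimated correlation). Rsad2 (-2.59), Gfap (-1.91 ± 0.09) and Aqp4 (-1.58) lay below the sum, and Glul (0.86) above it.

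Of 20 cholesterol synthesis genes, 10 lay above the sum and 0 below it (12 and 0 adjusted over the list alone). Camera called the cholesterol synthesis list higher (adjusted p = 0.000363, and adjusted p = 0.247 with an estimated correlation). Of 21 p53 target genes, 8 lay above the sum and 1 below it (9 and 2 adjusted over the list alone). Camera called the p53 target list higher (adjusted p = 0.00178, and adjusted p = 0.179 with an estimated correlation). Of 28 lysosome and endocytosis genes, 8 lay above the sum and 1 below it (8 and 1 adjusted over the list alone). Camera called the lysosome and endocytosis list higher (adjusted p = 0.0482, and adjusted p = 0.513 with an estimated correlation). Dhcr7 (0.69), Gadd45a (1.34), Cdkn1a (0.66) and Npc1 (0.70) lay above the sum, and Btg2 (-1.11) and Psap (-0.28) below it. The microglia genes moved beside these groups with a median of -3.02. The lysosome call ended without control replicate 1 (adjusted p = 0.104), piezoelectric replicate 2 (0.113), ultrasound replicate 1 (0.0818), ultrasound replicate 2 (0.0504) or nanosticker replicate 2 (0.0744). edgeR called 3350 genes, 1692 above and 1658 below the sum, against 2201 in all by DESeq2. Library size alone gave 1516 above and 1866 below. The named departures upward included Tnn (4.26), Sostdc1 (3.88), Casr (3.52) and Krt19 (3.20). Downward they were Ttr -6.55, Prokr2 -5.32, Amer3 -3.76 and Dlx1 -3.62, with Zbtb33, which had no counts in the nanosticker libraries.

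Sox2 (0.55) and Olig2 (0.40) lay above the sum and Nes (-0.76), Tubb3 (-1.23), Dcx (-1.24) and Cacna1c (-0.47) below it. For Map2 (-0.15), Rbfox3 (-0.23), Mki67 (0.03), Fos (0.18), Bdnf (-0.40) and Piezo1 (0.19) no departure was detectable. The call of Cacna1c ended without nanosticker replicate 1 (adjusted p = 0.0799), piezoelectric replicate 1 (0.0609) or ultrasound replicate 1 (0.0611), with the length trend removed (0.275) and by DESeq2 (0.0968). That of Tnn ended without control replicate 2 (adjusted p = 0.0517). Zbtb33 was not called without nanosticker replicate 1 (adjusted p = 0.0662), nanosticker replicate 2 (0.0683), piezoelectric replicate 1 (0.115) or piezoelectric replicate 2 (0.101), nor without a filter on low counts (0.0703).

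The 3 comparisons with control share the control libraries, which alone makes their fold changes correlate. Across genes, which are not independent replicates, piezoelectric and ultrasound changes correlated at Pearson r = 0.589, piezoelectric and nanosticker changes at 0.296 and ultrasound and nanosticker changes at 0.408. In 100 simulated sets of unchanged groups the values were 0.498, 0.497 and 0.499. The covariances were 0.0702, 0.0594 and 0.0963, against simulated values of 0.0375, 0.0376 and 0.0377. On genes with whole counts they were 0.0418, 0.0402 and 0.0783, against 0.0219 in each simulation. The simulation gave all groups the same spread and no length trend. The control libraries lay farther apart (53.5) than those of the other groups (44.2 to 45.3), so the simulated covariances may be too low. Ultrasound and nanosticker shared 384 higher and 263 lower genes, where independent lists would share 114 and 80.3, and 153 genes changed in opposite directions. Igf2, Lcn2, Ccl2, Fos, Junb, Lum, Col3a1, Mbp and Mag rose in both groups and Gja1 fell in both, whereas Sox10, Gfap and Rsad2 moved in opposite directions. Piezoelectric and ultrasound shared 19 and 10 (expected 0.927 and 0.316). Piezoelectric and nanosticker shared 15 and 9 (expected 4.55 and 1.77), with 3 opposite. The controls were not split, since each part would hold 1 library, and part of the excess may come from the shared controls.

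The authors' deposited table gives its own DESeq2 q-values for 5 of these comparisons. At q below 0.05, the authors' deposited table calls 39 genes for piezoelectric against control, 380 for ultrasound and 2795 for nanosticker. For nanosticker against piezoelectric and against ultrasound, the authors' deposited table calls 3780 and 3478. Of these, 20, 364, 2768, 3555 and 3284 were also called by edgeR, all in the direction given by the authors' deposited table.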

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

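The tests with the length trend removed, those on genes with whole counts and the other settings of distances and correlations were chosen after the result was seen, while the remaining alternatives were planned. Over named genes and settings, values without 1 library numbered 2976 on the same side of the threshold and in the same direction, 120 that no longer passed, 42 that newly passed and 22 that turned. Under the other settings they numbered 3750, 61, 40 and 5. No called gene turned. Camera with an estimated correlation, which allows genes of a list to vary together, called 0 of the 33 lists fixed in advance in each of the 6 comparisons at an adjusted p below 0.05. At an unadjusted p below 0.05 it called 4 for piezoelectric, 6 for ultrasound, 5 each for nanosticker against control, piezoelectric and ultrasound, and 6 for additivity. The cause was not tested for any other value below, except that fits with fewer libraries or groups have fewer degrees of freedom. Depth limits genes near the count filter, such as Bdnf and the microglia genes.

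Against the count of 33, piezoelectric calls were 20 by limma-voom, 81 without a filter, 10 with only the groups compared, 138 with the length trend removed, 66 on genes with whole counts and 13 to 1131 without 1 library. Ultrasound calls (1031) became 636 by DESeq2, 478 with only the groups compared, 1584 with the length trend removed and 377 to 2192 without 1 library. Nanosticker against ultrasound (4938) ranged from 3199 to 6251 without 1 library, and the departure from additivity (3350) gave 2201 by DESeq2. Which of higher and lower calls were more numerous turned with library size alone in all comparisons but piezoelectric against control. It also turned for ultrasound with the length trend removed (788 and 796), for nanosticker against ultrasound without control replicate 1 (3085 and 3164) or 2 (3114 and 3137), and for additivity with a stricter filter (1638 and 1652) and without control replicate 1 (2068 and 2180), control replicate 2 (2204 and 2509) or piezoelectric replicate 2 (1270 and 1279). Of the higher counts with the length trend removed, 32 of the 33 piezoelectric calls and 1015 of the ultrasound calls were shared with the planned fit. Fry, which asks whether the genes of a list move, on balance, 1 way and does not compare them with other genes, called 3 lists for piezoelectric, 21 for nanosticker, 23 for nanosticker against piezoelectric, 17 against ultrasound and 18 for additivity, where camera called 7, 8, 8, 9 and 7. Without 1 library, camera called 9 to 13 lists for nanosticker against piezoelectric and 6 to 11 for additivity. Without a filter, camera did not call the synapse (adjusted p = 0.159) and cholesterol (0.0630) lists for piezoelectric or the mechanosensitive channel (0.0642) and immediate early (0.0585) lists for ultrasound. On genes with whole counts it did not call these last lists (0.0673 and 0.0990) or the lysosome list for nanosticker against ultrasound (0.125) and additivity (0.136).

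The correlation of piezoelectric and nanosticker changes was 0.345 without a filter and 0.264 to 0.487 without 1 library, that of piezoelectric and ultrasound changes 0.502 to 0.758, and that of ultrasound and nanosticker changes 0.369 to 0.537. The covariances of 0.0702, 0.0594 and 0.0963 became 0.105, 0.0971 and 0.143 without control replicate 1. Without control replicate 2 the covariances became 0.170, 0.158 and 0.182. The control libraries lay 69.7 apart without a filter, where more genes enter the distance, and 34.6 on genes with whole counts, where fewer do.

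The values that turned direction all belong to genes that passed no test in that comparison. Without 1 library, log2 fold changes of Bdnf ran from -0.20 to 1.75 for piezoelectric, -0.20 to 1.76 for ultrasound and -0.28 to 1.81 for nanosticker against control, from -0.75 to 0.59 for nanosticker against piezoelectric and also against ultrasound, and from -1.70 to 0.27 for additivity. By limma-voom Bdnf was -0.034 for nanosticker against piezoelectric and -0.038 against ultrasound. For piezoelectric against control the ranges were -0.043 to 0.13 for Dcx, -0.024 to 0.089 for Olig2, -0.25 to 0.23 for Piezo1, -0.34 to 0.014 for Rbfox3 and -0.089 to 0.11 for Tubb3. Dcx was -0.014 with the length trend removed and Tubb3 -0.0021 with library size only. For additivity the ranges were -0.15 to 0.19 for Mki67, -0.063 to 0.41 for Piezo1 and -0.49 to 0.0034 for Rbfox3, and Mki67 was -0.0035 with library size only.

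The replicate number as a block gave 27, 793, 4973, 4824, 4560 and 2965 genes for the 6 comparisons in the order of the report, each within 1.5 times the count without it. Deviations of libraries with the same number correlated at -0.136 to 0.135 between groups. These values show no clear pairing, but 2 libraries per group cannot exclude it, and the labels do not mention pairing. With the block, 7 named calls (adjusted p from 0.0511 to 0.119) ended for piezoelectric, 2 (adjusted p from 0.0637 to 0.0813) for ultrasound and that of Zbtb33 for additivity (adjusted p = 0.0783). The mechanosensitive channel list for ultrasound (camera adjusted p = 0.0564) and the lysosome list for additivity (0.0521) were not called with it, and no other call of a named gene or list ended.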

Other observations

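The tests of sequencing depth, of scaling, of the transcript length trend in the microglia and oligodendrocyte genes and as the whole or part of the control difference, and of a lower share of other cells were chosen after the result was seen, whereas those of the length trend over all control genes, of other cell types in a control, of further microglia genes, of Schwann cells, of lineage stages and of GABAergic genes were stated before their values were looked at. Further lists, drawn up from general knowledge once the comparisons had been seen, separate stages of the oligodendrocyte lineage, counting only genes outside the 33 lists, and the members named were chosen after their values were seen. Camera p-values of all further lists were adjusted over the further lists alone, a smaller family than the 33 lists. In the nanosticker group against control, genes of newly formed oligodendrocytes rose (8 higher and 0 lower of 9, median log2 fold change 1.07, camera adjusted p = 1.39e-05, and adjusted p = 0.0546 with an estimated correlation), such as Enpp6 (1.78), Rras2 (1.65) and Sirt2 (1.10), and so did genes of mature oligodendrocytes (7 higher and 1 lower of 10, median log2 fold change 0.87, camera adjusted p = 0.000437, and adjusted p = 0.0694 with an estimated correlation), such as Apod (2.17), Pllp (1.90) and Aspa (1.5), with Mal lower (-0.36). Precursor genes were not called (2 higher and 0 lower of 9, median log2 fold change 0.29, camera adjusted p = 0.0856, and adjusted p = 0.336 with an estimated correlation). A hypothesis that late genes rose more than precursor genes had a difference of medians of 0.58 (two-sided permutation test over 10 and 9 genes, 1e+05 resamples, p = 0.0421), which is consistent with it, although genes are not independent replicates. In the ultrasound group mature genes were higher (6 higher and 0 lower of 10, median log2 fold change 0.39, camera adjusted p = 0.000652, and adjusted p = 0.104 with an estimated correlation), such as Apod (1.04), and newly formed genes lower (0 higher and 3 lower of 9, median log2 fold change -0.20, camera adjusted p = 0.00519, and adjusted p = 0.104 with an estimated correlation), such as Enpp6 (-0.72). With an estimated correlation, newly formed genes were called higher for nanosticker against ultrasound (camera adjusted p = 0.0390) and above the sum for additivity (adjusted p = 0.0344). These values cannot be set beside those of the 33 lists, which were adjusted over more lists and of which none was called in this way. The list was also drawn up after the rise of oligodendrocyte genes had been seen.

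A second hypothesis was that the nanosticker group lost GABAergic interneuron transcripts as a set, as the decreases of Dlx1, Dlx5, Gad1 and Slc32a1 might suggest. Further GABAergic genes were lower as a set (3 higher and 12 lower of 19, median log2 fold change -0.62, camera adjusted p = 0.00409, and adjusted p = 0.0694 with an estimated correlation), with the transcription factor gene Sp8 (-2.89) and the peptide gene Cck (-2.76) lower, but the median of -0.62 missed the bound of -1 set for it and Sst (2.95), Npy (1.21) and Prox1 (1.02) were higher, so the hypothesis stays open. Projection neuron genes were not called (3 higher and 5 lower of 11, median log2 fold change -0.95, camera adjusted p = 0.147, and adjusted p = 0.361 with an estimated correlation), with Bcl11b lower (-2.30) and Fezf2 higher (2.24).

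Control replicate 1 stood apart from control replicate 2, and the piezoelectric and ultrasound counts rose without either of them. Unequal depth is argued against by a ratio of totals of 1.00, and a transcript length trend as the whole difference by a ratio of 1.55 between the control SD and the highest SD of the other groups on genes with whole counts after its removal. The length trend may be part of it, as the Spearman correlation with length was -0.60 in the control libraries alone. The test over all genes stated in advance decides nothing, since its ratio of 1.08 after removal was already inside its bound before removal, where genes with shared reads set the spread. Cells of another type in 1 control stay open, the cell type list farthest from 0 being microglia at 0.17 ± 0.083 (bootstrap SD), and no other biological explanation was tested.

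Microglia and macrophage genes were lower in the nanosticker group. The median stayed at -3.46 or below under 3 scalings and was -3.51 with the transcript length trend removed. Both tests could hardly have come out otherwise. The scalings moved the median of all tested genes only from 0.0064 (TMM) to -0.056 (library size alone). Nanosticker fold changes correlated with length at Spearman -0.017 across 10178 better expressed genes. The choice among these scalings and the length trend are thus too small to account for the fall of the microglia genes. Fewer microglia or macrophages in these cultures may account for it: of 27 further genes, none on the 33 lists, 19 were tested, 12 fell and 1 (Rnase4, 0.32) rose (median -2.06, camera adjusted p = 3.18e-05, and adjusted p = 0.0869 with an estimated correlation), such as Cd53 (-4.65) and Rac2 (-3.36). That share of 63.2% missed the 80% set in advance, and levels in control were low (median 3.84 CPM). A lower expression per cell was not tested, so a lower number of such cells stays open, as does the treatment.

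Oligodendrocyte genes rose while astrocyte genes fell in the nanosticker group. The transcript length trend is argued against, since nanosticker fold changes hardly correlated with length (Spearman -0.017 across 10178 genes). The oligodendrocyte median was 1.13 with the trend removed. A loss of other cells that would raise every remaining type alike is contrary to the astrocyte median of -0.52. That median is part of the pattern itself, so this test decides nothing further. A loss of astrocytes or neurons that raises the share of oligodendrocytes was not tested. Schwann cells as a source of part of the myelin transcripts stay open. Of 13 Schwann genes, 7 were tested (2 of the 13 are on the 33 lists), and their median was 0.91, between the bounds set in advance. Erbb3 (2.41) and Pmp2 (1.82) were higher and L1cam (-1.94) and Drp2 (-0.68) lower. Of 17 oligodendrocyte genes tested, 16 rose. That list holds genes that oligodendrocytes express and Schwann cells do not, such as Olig2, Nkx2-2, Mog and Opalin. This argues against Schwann cells as the only source. The treatment itself, acting on the fate or survival of cells, stays open and untested.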
